A study of Homo sapiens with 22 samples.

How the data were processed

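RNA of NALM6 leukaemia cells recovered from SCID mice was measured on Affymetrix Clariom D human arrays, 1 array per sample, with 22 arrays in all. Per the labels, marrow cells were aspirated from the femur and CSF cells from the spine, passed through a 70 µm filter and freed of red cells by ACK lysis. The labels name no step that sorts human from mouse cells. RNA was extracted with RNeasy columns, checked on a Bioanalyzer and a Nanodrop, and labelled with biotin using the WT Plus kit. The deposited values are on the log2 scale, and per the submitters' processing notes they were made with RMA, which corrects background, normalizes between arrays and summarises probes, in Affymetrix Expression Console. The versions of these tools and the genome build of the probes are not given in the sources used here, so no coordinates are printed. The medians of the 22 arrays over the whole table lay between 5.04 and 5.22, no value was missing, and no arrays were identical.

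Of the 138745 features of the table, 2995 were control features and 135750 transcript clusters. The platform's annotation listed 36176 clusters with 1 gene symbol, 1119 with several and 98455 without a gene. Genes were tested by symbol, and of the 1576 symbols with more than 1 cluster the cluster of highest mean over all arrays was kept, which left 33616 genes, 17375 of them protein coding. No low-level filter was applied. Groups were read from the sample titles: 6 control marrow, 6 treated marrow, 6 control CSF and 4 treated CSF arrays. The labels do not say whether marrow and CSF arrays came from the same mice. Gene residuals of arrays with equal replicate numbers did not pair them: the correlations ran from -0.199 to 0.302 in control mice and from -0.464 to -0.0491 in treated mice. This cannot show that they came from different mice, since the numbers may have been given anew at each site. The arrays were handled as independent, an assumption on which the comparisons between sites and the average over sites rest. Each gene's p rests on a single spread between arrays, pooled within the 4 groups of both sites and moderated. The p values of marrow therefore also depend on the CSF arrays, and the reverse. Because mice were treated until the clinical endpoint, harvest times may differ between groups and are not given in the sources used here. The number of arrays limits the precision: the median SE of a log2 fold change was 0.135 in marrow, 0.151 in the CSF and 0.203 for the difference of both.

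A means model of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation without trend, 18 residual and 8.58 prior degrees of freedom, and two-sided tests. P values were adjusted by Benjamini and Hochberg over all genes within each comparison, with a threshold of 0.05. The comparisons were treated against control in marrow, the same in the CSF, CSF against marrow in control mice, the same in treated mice, and the difference of both treatment effects. Gene lists from textbook knowledge, 29 of biology, 4 of RNA quality or handling and 12 of other cell types, 1142 listed genes in all, were tested with camera of limma, a competitive test, with a preset correlation of 0.01, at least 5 measured members, and adjustment over the 45 lists. Camera with an estimated correlation and fry, a test of each list on its own, were run beside it. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

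Genes were named by a fixed rule. For treatment at each site and for site in control mice it took up to 10 higher and 10 lower genes of largest change with an adjusted p below 0.05, groups without overlap and a higher group's mean of at least 5.98 on the log2 scale, the median of all gene means. For site in treated mice and for the difference of the treatment effects it took 5 and 5, without the overlap condition in the latter. Where none passed, the 5 of smallest p in each direction were taken as not passing. Small RNAs, uncharacterised loci, antisense transcripts, pseudogenes with their parent on the array, immunoglobulin and T cell receptor segments, olfactory receptors, XIST and Y-linked genes were not named unless as list members, and 4 genes of smallest p near or below the level of the background probes were left out of the text. For each list discussed, up to 4 members past the threshold or 2 of smallest p were added, and ITGA6 and PIK3CD were always named.

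The alternatives were a fit on only the groups compared, trended and robust moderation, array weights, only the upper part of genes by mean, quantile normalization or median centring on top of the deposited values, the mean of a gene's clusters, all clusters of the table, a fold of at least 2, replicate number as a block, and each array left out in turn. After seeing the data, further alternatives were added, which left out control CSF replicate 1 and treated CSF replicate 2 together, or took the intronic control level or the poly-A spike level as a covariate. Fits on only the arrays of low or of high intronic level were also run then and removed, because they split the samples by a measured value, and their results are not reported. The treatment effect averaged over both sites was added as a comparison in the same way. In simulated data of the same size with 50 changed genes per effect size, the test recovered 98% of genes changed by a log2 value of 1 in marrow, 90% in the CSF and 72% for the difference of the treatment effects, and 36%, 26% and 6% of those changed by 0.5. Between 2.86% and 7.07% of the calls were false. The simulation drew normal noise independently for each gene, without correlation between genes and without a divergent array. Many changed genes also make the adjusted threshold easier to pass. These shares therefore describe the test under such conditions and may not hold for the real arrays. Clusters with several symbols or none are not counted among the genes of the report, and were tested apart and in the alternative with all clusters.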

Results

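RNA of NALM6 cells, a human B-cell acute lymphoblastic leukaemia line, was measured on 22 Affymetrix Clariom D human arrays after the cells had grown in SCID mice. The cells came from the bone marrow, aspirated from the femur, or from the cerebrospinal fluid (CSF), aspirated from the spine. Treated mice received a compound that the labels abbreviate as PI3Kd, known from the study as an inhibitor of the delta form of phosphoinositide 3-kinase (PI3K), at 2 mg/kg in 2 doses per day until the clinical endpoint. The arrays fell into 6 of control marrow, 6 of treated marrow, 6 of control CSF and 4 of treated CSF. Each array was handled as 1 mouse, and the number of arrays limits the precision of every value. The median array value over the 33616 genes tested lay between 5.91 and 6.09 on the log2 scale. The design asks how the inhibitor changes the leukaemia cells at each site, how cells in the CSF differ from those in the marrow, and whether the effect of the inhibitor differs between the sites.

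Treated CSF replicate 2 stood apart from the other 21 arrays. Its median correlation with them across genes was 0.967, against 0.984 for control CSF replicate 1 and 0.987 to 0.991 for the rest. Its poly-A spikes, bacterial transcripts added in a fixed amount before amplification, averaged 9.99 on the log2 scale, and no other array was above 8.27. Its values spread less over all genes, with an SD of 2.07, than those of the control marrow arrays, whose SD averaged 2.32. Intronic control probes averaged 3.46 ± 0.06 (SD, n = 6) in control marrow and 3.77 ± 0.09 (SD, n = 6) in control CSF, without overlap between both groups. In treated mice they averaged 3.59 ± 0.19 (SD, n = 6) in marrow and 3.62 ± 0.18 (SD, n = 4) in CSF. The intronic level therefore moved with the site in control mice. It was also uneven between treated and control marrow. Treated marrow replicates 2, 5 and 6 were at 3.77, 3.78 and 3.75, above all control marrow arrays, which reached 3.52. Treated marrow replicates 1, 3 and 4 were no higher than 3.45. Hybridisation spikes ranged from 10.94 to 11.01 in control marrow and from 11.09 to 11.41 in control CSF, without overlap. In treated marrow they ranged from 10.98 to 11.45. Poly-A spikes averaged 7.01 in control marrow and 7.63 in control CSF. In treated mice the poly-A means were 7.30 in marrow and 8.27 in CSF, the latter with treated CSF replicate 2. Control marrow thus differed in control features from both groups it was compared with.

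**Figure D1:**
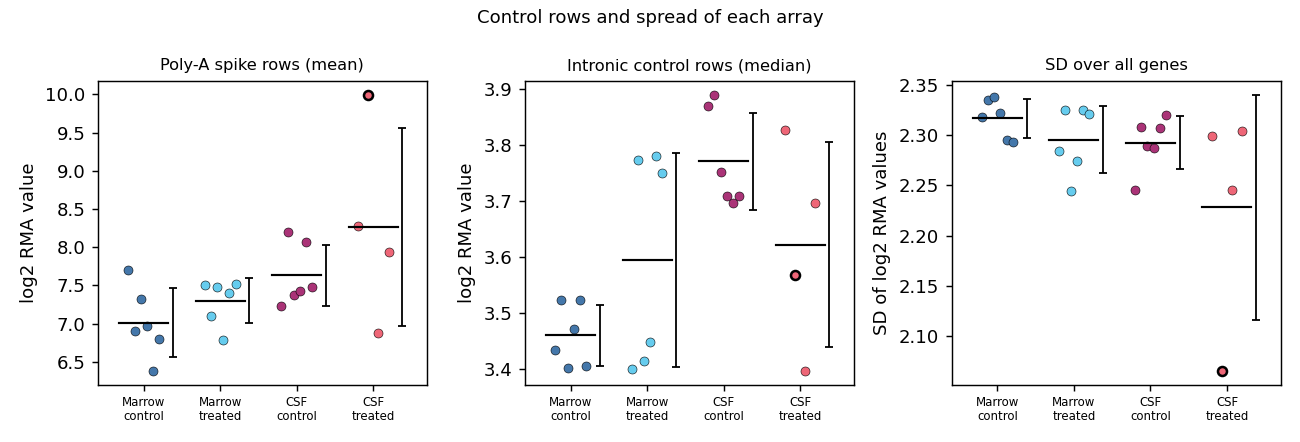
Mean of the poly-A spikes, median of the intronic control probes and SD over all genes for each of the 22 arrays (log2 values, points) by group, with the group mean as a line and its SD as a bar. The heavy ring marks treated CSF replicate 2, whose poly-A spikes averaged 9.99.

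In bone marrow, CLECL1, AK5, CD96 and TTN were lower and FYN and MYOF higher in mice given the inhibitor, although no gene passed the threshold after adjustment. CLECL1, a C-type lectin-like protein of B cells and dendritic cells, averaged 7.15 ± 0.25 (SD, n = 6) in control marrow and 5.25 ± 0.88 (SD, n = 6) in treated marrow. This 3.73-fold lower level had every one of the 6 treated arrays below all control arrays. AK5, an adenylate kinase, was 2.29-fold lower and TTN, which encodes titin, 1.85-fold lower, each again without overlap between the groups. CD96, an immunoglobulin-superfamily receptor best known from T and NK cells, was 2.41-fold lower, with 5 of 6 treated arrays below the control range. FYN, a Src-family kinase, was 1.76-fold higher, with 5 of 6 treated arrays above the control range, and MYOF, the membrane protein myoferlin, had a log2 fold change of 0.76 ± 0.14 (SE), with all 6 above it.

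The limma test gave 0 genes past an adjusted p of 0.05 in marrow. At an unadjusted p below 0.05 there were 1637 genes, 843 higher and 794 lower, 4.87% of those tested. Evenly spread p values give 5%, whereas other random splits of the same arrays gave a median of 1080 genes. Of 100 splits, the real one included, 9 gave as many as the real one. The smallest adjusted p was 0.0543. That value belonged to CLECL1, with a log2 fold change of -1.90 ± 0.32 (SE), and to AK5, at -1.19 ± 0.20 (SE). TTN had a log2 fold change of -0.89 ± 0.16 (SE, adjusted p = 0.0546 in limma), and CD96 one of -1.27 ± 0.23 (SE, adjusted p = 0.0622 in limma). TMC8 came next among the lower genes, at -0.62 ± 0.12 (SE, adjusted p = 0.0924 in limma), lower than all controls in 6 of 6 treated arrays. Among the higher genes, MYOF had an adjusted p of 0.0892, and FYN (0.82 ± 0.18, SE) and HSPA2, an Hsp70-family chaperone (0.57 ± 0.12, SE), had an adjusted p of 0.213 in limma. ATP1B1, a subunit of the sodium-potassium pump, was at 0.76 ± 0.17 (SE, adjusted p = 0.239 in limma) and THAP2 at 0.95 ± 0.21 (SE, adjusted p = 0.247 in limma). Both were dim in control marrow, with levels of 4.48 to 5.56 for ATP1B1 and 4.06 to 5.35 for THAP2. The count was not stable at 0: it was 6 without treated CSF replicate 1, 5 without treated marrow replicate 2 and 4 without treated marrow replicate 6. It was 1 to 3 without treated marrow replicate 5, control CSF replicates 4 or 5, or treated CSF replicates 2, 3 or 4.

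Of the 45 gene lists, 8 passed the camera test in treated against control marrow, 2 higher and 6 lower. None of the 8 passed with a correlation estimated from the data, each having an adjusted p = 0.93 with an estimated correlation. At the preset correlation, heat shock proteins rose, with 12 of 14 members higher and a median log2 fold change of 0.19 (adjusted p = 4.61e-04). HSPH1, an Hsp110 chaperone, was at 0.72 ± 0.21 (SE) and CHORDC1, an Hsp90 cochaperone, at 0.43. Targets of MYC and ribosome biogenesis factors fell, with 23 of 26 members lower and a median of -0.11 (adjusted p = 5.99e-04), as NOP16 at -0.32 and PES1 at -0.26. Cytosolic ribosomal proteins fell, lower in 22 of 23 members, with a median of -0.088 (adjusted p = 5.99e-04), among them RPS9 at -0.17. Nuclear-encoded subunits of oxidative phosphorylation fell, lower in 25 of 30 members (median -0.11, adjusted p = 0.00296). Targets of ATF4, the transcription factor of the amino acid response, fell, lower in 19 of 25 (median -0.11, adjusted p = 0.00296). SLC7A5, an amino acid transporter, was at -0.54 ± 0.20 (SE) and WARS1, a tRNA synthetase, at -0.38. MHC class II genes fell with a median of -0.12 over 13 members, 11 of them lower (adjusted p = 0.0356), and HLA-DQA1 was at -0.43. B lineage genes fell, lower in 21 of 27 members, with a median of -0.076 (adjusted p = 0.0435), CD72 being at -0.41 and CD79A at -0.34. Axon guidance genes rose by a median of 0.046, with 38 of 58 members higher (adjusted p = 0.0435), PLXNC1 at 0.32 in 6 of 6 treated arrays above all controls.

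For the marrow effect fry, which tests each list alone, gave 0 lists. In limma adjusted over the list alone, 1 heat shock gene was higher and 0 genes of the other 7 lists passed, which at an unadjusted p below 0.05 held at most 3 genes each. The heat shock, MYC and ribosomal protein lists stayed past the threshold with any 1 of the 22 arrays left out. Of the 22 single omissions, the oxidative phosphorylation, ATF4, MHC class II, B lineage and axon guidance lists passed in 21, 20, 17, 16 and 14. Their highest adjusted p in camera was 0.0816 without control marrow replicate 4 for the first, 0.059, 0.456 and 0.215 without treated marrow replicate 3 for the next, and 0.161 without control marrow replicate 2 for the last. The 8 lists became 4 without control marrow replicate 2 or treated marrow replicate 3 and 5 without treated marrow replicate 5, and quantile normalization ended oxidative phosphorylation (0.1), MHC class II (0.155), axon guidance (0.1) and B lineage (0.295).

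In the CSF, AK5, CD96, CLECL1 and TTN fell under the inhibitor and FYN rose, each past the threshold. AK5 fell by 1.73 on the log2 scale (SE 0.23, 3.32-fold lower, adjusted p = 0.00134 in limma), from 7.48 ± 0.45 (SD, n = 6) in control CSF to 5.75 ± 0.40 (SD, n = 4) in treated CSF. CD96 fell by 1.74 (SE 0.26, 3.34-fold lower, adjusted p = 0.00399 in limma), from 9.71 ± 0.23 (SD, n = 6) to 7.97 ± 0.52 (SD, n = 4). CLECL1 fell by 2.03 (SE 0.35, 4.08-fold lower, adjusted p = 0.0158 in limma) and TTN by 1.25 (SE 0.18, 2.38-fold lower, adjusted p = 0.00275 in limma). FYN rose 2.08-fold, from 7.20 ± 0.31 (SD, n = 6) to 8.26 ± 0.29 (SD, n = 4), with an adjusted p of 0.0232 in limma. For each of these genes all 4 treated arrays lay outside the range of the 6 control arrays, as the naming rule required. Among all genes tested, 191 higher and 541 lower ones had no overlap between these groups.

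**Figure D2:**
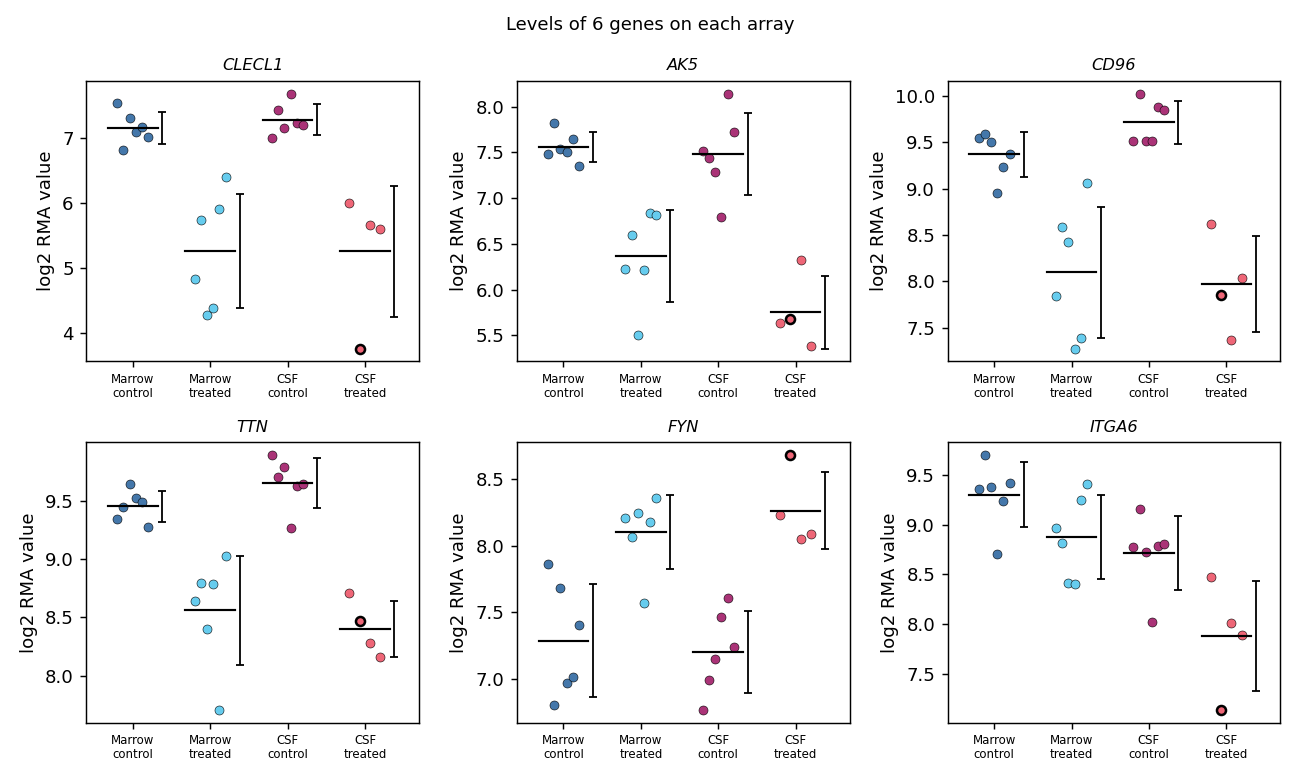
Levels of CLECL1, AK5, CD96, TTN, FYN and ITGA6 on each of the 22 arrays (log2 RMA values, points) by group, with the group mean as a line and its SD as a bar, and a heavy ring at treated CSF replicate 2. CLECL1, AK5, CD96 and TTN were lower and FYN higher in treated mice at both sites, with an adjusted p below 0.05 in the CSF.

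In all, limma called 36 genes in the CSF, 6 higher and 30 lower, of which 16 changed at least 2-fold. At an unadjusted p below 0.05 there were 4403 genes, 1544 higher and 2859 lower, which is 13.1% of those tested. SPP1, which encodes the secreted matrix protein osteopontin, fell 2.42-fold, from 7.63 ± 0.22 (SD, n = 6) to 6.36 ± 0.45 (SD, n = 4), with an adjusted p of 0.0158 in limma. PTPN22, a lymphocyte phosphatase, fell by 1.08 (SE 0.19, adjusted p = 0.0158 in limma), and PTPRC, the phosphatase CD45, fell by 1.03 (SE 0.16, adjusted p = 0.00739 in limma). CROT, a peroxisomal carnitine acyltransferase, fell 2.29-fold (adjusted p = 0.0212 in limma). ID2, an inhibitor of DNA-binding transcription factors, fell by 1.19 (SE 0.22, adjusted p = 0.0243 in limma) and ADAMTS9, a secreted metalloprotease, by 1.14 (SE 0.21, adjusted p = 0.0198 in limma). BTG3, an antiproliferative protein, fell by 1.04 (SE 0.19, adjusted p = 0.0205 in limma), from 7.18 ± 0.18 (SD, n = 6) to 6.14 ± 0.71 (SD, n = 4). In each of these 7 genes the 4 treated arrays lay below all 6 controls, which the naming rule required of genes taken by size of change. Without treated CSF replicate 2 the count was 7 genes, which held AK5, CD96, TTN, BTG3 and PTPRC. CLECL1 (adjusted p = 0.113), FYN (0.142), SPP1 (0.123), CROT (0.135), ID2 (0.123), ADAMTS9 (0.123) and PTPN22 (0.0855) then no longer passed in limma. All kept their direction, with log2 fold changes of -1.53 for CLECL1, 0.92 for FYN, -1.11 for SPP1, -0.92 for CROT and -0.90 for ADAMTS9. ID2 and PTPN22 came no nearer to 0 than -1.03 and -1.0 in any single omission, and BTG3 was at -0.69 without that array. Left out singly, control CSF replicates 1, 2, 3, 5 and 6 gave 19, 6, 23, 16 and 14 genes, treated CSF replicates 1, 3 and 4 gave 98, 20 and 36, and control marrow replicate 6 gave 23. The share higher moved as well, from 6 of 36 to 22 of 98 without treated CSF replicate 1 and to 15 of 36 without replicate 4. Fitting only the groups compared gave 7 genes, array weights 11 and replicate number as a block 6. The intronic and poly-A levels as covariates, chosen after seeing the data, gave 4 and 6.

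Lists of metabolism and cell division were lower in treated than in control CSF. By camera, 15 of the 45 lists passed, 1 higher and 14 lower. None of the 15 did with an estimated correlation, where the smallest value was an adjusted p = 0.609 with an estimated correlation, nor with fry. Nuclear-encoded oxidative phosphorylation genes fell, lower in 30 of 30 members, with a median of -0.22 (adjusted p = 7.35e-08). NDUFV2, a complex I subunit, was at -0.59 ± 0.13 (SE, adjusted p = 0.0543 in limma), and CYCS, cytochrome c, at -0.43. MYC targets and ribosome biogenesis factors fell, lower in 26 of 26 members with a median of -0.26 (adjusted p = 4.49e-07), such as LYAR at -0.59 and TFRC, the transferrin receptor, at -0.52. S phase genes (median -0.20, adjusted p = 5.50e-07) and G2 and M phase genes (median -0.22, adjusted p = 1.37e-06) fell, each lower in 28 of 28 members. CLSPN, a checkpoint adaptor, was at -0.43, MCM6, a replicative helicase subunit, at -0.33, and CDK1, the mitotic kinase, at -0.36. Replication-dependent histones fell, lower in 23 of 23 (median -0.20, adjusted p = 2.02e-04), among them H3C8 at -0.31. ATF4 targets fell, lower in 23 of 25 (median -0.29, adjusted p = 2.18e-05), with ATF3 at -0.61 and CHAC1, which degrades glutathione, at -0.53. Glycolysis genes fell, lower in 17 of 19 (median -0.21, adjusted p = 6.82e-05), with SLC2A3, a glucose transporter, at -0.78, and HK1, a hexokinase, at -0.68. Genes of the hypoxia response fell, lower in 20 of 26 (median -0.17, adjusted p = 0.00887), with FAM162A at -0.44.

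Lists of B lineage, B cell receptor, interferon and MHC class I genes were also lower in treated CSF by camera. None of the lists that follow passed with an estimated correlation, where their smallest value was an adjusted p = 0.609 with an estimated correlation and their largest 0.675. B lineage genes fell, lower in 20 of 27 members (median -0.16, camera adjusted p = 0.00507), with CD72, a B cell coreceptor, at -0.86 ± 0.19 (SE, adjusted p = 0.0631 in limma) and MS4A1, which encodes CD20, at -0.71. Kinases and regulators of B cell receptor signalling fell, lower in 17 of 25 (median -0.14, camera adjusted p = 0.0279), although the called members moved apart, PTPRC lower and FYN higher. Interferon-stimulated genes fell, lower in 25 of 36 (median -0.17, camera adjusted p = 0.0139), with IFITM1 at -0.81 ± 0.18 (SE, adjusted p = 0.0652 in limma) and IFITM3 at -0.62, both membrane proteins that restrict virus entry. Genes of MHC class I and antigen processing fell, lower in 13 of 15 (median -0.18, camera adjusted p = 0.0315), B2M being at -0.24 and TAP2 at -0.32. Cytosolic ribosomal proteins fell, lower in 23 of 23 (median -0.13, camera adjusted p = 0.00708), with RPL5 at -0.58 and RPL37 at -0.21. Small nucleolar RNAs fell, lower in 25 of 31 (median -0.21, camera adjusted p = 0.00597), with SNORA1 at -0.74 and, against that direction, SNORD95 at 0.77. The list that rose held markers of neutrophils and their precursors, with 20 of 25 members higher (median 0.19, camera adjusted p = 0.00507). FPR2, a formyl peptide receptor, was at 0.98 ± 0.22 (SE, adjusted p = 0.0806 in limma) and NCF1, an oxidase subunit, at -0.53. Adjusted over the list alone, limma gave 11 lower MYC targets, 6 lower glycolysis genes, 5 lower hypoxia genes, 4 lower genes each for oxidative phosphorylation and S phase, 3 lower interferon-stimulated genes and 2 lower B lineage genes. It gave 5 lower and 1 higher gene of B cell receptor signalling, and 1 higher gene each for neutrophils and small nucleolar RNAs. The number was 0 for the G2 and M phase, histone, ATF4, ribosomal protein and MHC class I lists, where 9, 2, 11, 1 and 1 lower members had an unadjusted p below 0.05.

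Treated CSF replicate 2, whose bright genes read lower and dim genes higher than on the other 3 treated CSF arrays (Spearman correlation across genes of deviation with level, -0.462), carried much of these list shifts. Without it the oxidative phosphorylation, MYC and S phase lists kept an adjusted p of 0.00765, ATF4 targets 0.0205 and histones 0.00189 in camera. G2 and M phase and glycolysis then had 0.0501, and the other 8 lists had 0.115 to 0.846 in camera. Members moved with it: without that array B2M was at -0.069, TAP2 at -0.11, CDK1 at -0.16, RPL37 at -0.10, RPL5 at -0.37 and HK1 at -0.40. CLSPN was then at -0.28, CYCS at -0.27, FAM162A at -0.29, LYAR at -0.38, IFITM1 at -0.54 and IFITM3 at -0.39. MHC class I and B cell receptor signalling passed in only 18 and 17 of the 22 single omissions. Heat shock proteins, which did not pass with all arrays (11 of 14 members higher, median 0.080, adjusted p = 0.0977), passed without that array (median 0.21, adjusted p = 0.00189 in camera). Quantile normalization on top of the deposited values ended the calls of G2 and M phase, histones, hypoxia, interferon-stimulated genes, MHC class I, B lineage, B cell receptor and ribosomal protein lists (adjusted p of 0.0524 to 0.778 in camera). It left MYC targets at 0.000867, ATF4 targets at 0.00586, oxidative phosphorylation at 0.00899 and S phase at 0.0191.

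**Figure D3:**
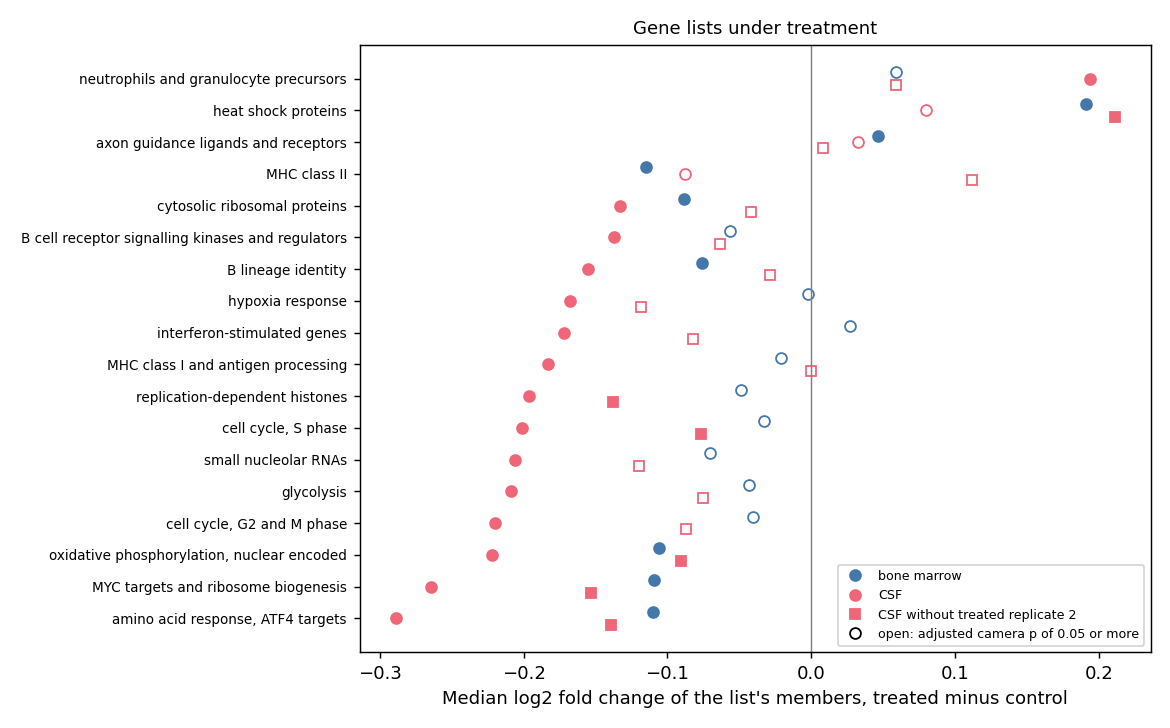
Median log2 fold change of the members of each of the 18 lists past the camera threshold in marrow or CSF (treated minus control), for marrow, for CSF, and for CSF without treated replicate 2. Filled symbols have an adjusted p below 0.05, and the CSF medians move toward 0 without that array for all lists drawn but heat shock proteins and MHC class II, the latter at -0.088 with it and 0.11 without it.

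The treatment effects at both sites shared direction across genes more often than not. Their log2 fold changes use no array in common, but mice may be shared between the sites. They had a Pearson correlation of 0.287 and a Spearman correlation of 0.247 across 33616 genes, which are not independent replicates. The sign was the same for 57.8% of genes. Of the 36 genes called in the CSF, 33 had the same sign in marrow, and 26 had an unadjusted p below 0.05 there. CLECL1, AK5, CD96, TTN and FYN had the same direction at both sites. A test of the difference between the sites gave 0 genes in limma, with 1551 at an unadjusted p below 0.05.

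**Figure D4:**
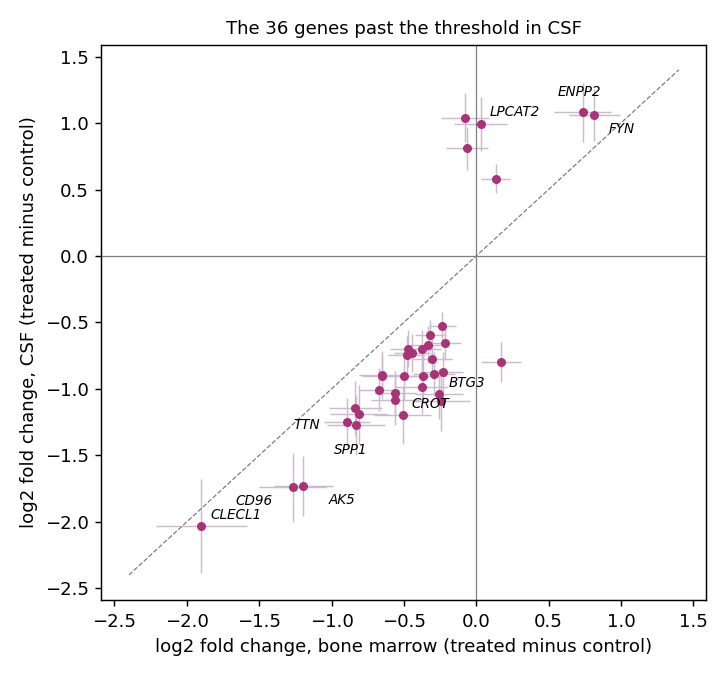
Log2 fold change (treated minus control) in marrow on the x axis and in CSF on the y axis for the 36 genes past the threshold in the CSF, with SE bars and a dashed line of equality. In marrow 33 of the 36 had the same sign as in the CSF.

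ITGA6, the laminin-binding integrin alpha 6 subunit, was lower in treated mice at both sites without passing the adjusted threshold. It was named in advance because it is known from the study as read from these arrays, so its values are not an independent finding. In marrow it averaged 9.30 ± 0.33 (SD, n = 6) in controls and 8.88 ± 0.42 (SD, n = 6) in treated mice, a log2 fold change of -0.43 ± 0.21 (SE, unadjusted p = 0.0515 and adjusted p = 1 in limma), with 5 of 6 treated arrays below the control mean. In the CSF it averaged 8.71 ± 0.37 (SD, n = 6) and 7.88 ± 0.56 (SD, n = 4), a log2 fold change of -0.84 ± 0.23 (SE, 1.79-fold lower, unadjusted p = 0.00135 and adjusted p = 0.167 in limma), with 4 of 4 treated arrays below the control mean and 3 below the control range. The difference between the sites, -0.41 ± 0.31 (SE), had an unadjusted p of 0.202 and an adjusted p of 0.916 in limma, and was -0.61 without treated CSF replicate 1 and -0.16 without replicate 2. PIK3CD, which encodes the catalytic subunit the inhibitor is aimed at, was at 0.35 ± 0.12 (SE, adjusted p = 0.792 in limma) in marrow and 0.20 (adjusted p = 0.513 in limma) in the CSF. Its CSF value was 0.11 without treated CSF replicate 1 and 0.32 without treated CSF replicate 2.

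None of the 25 integrin subunits measured passed in limma at either site, where 2 in marrow and 5 in the CSF, ITGA6 among the latter, had an unadjusted p below 0.05. When adjusted over the list alone, ITGA6 passed in the CSF, and 0 subunits did in marrow. The integrin list had a median of 0.067 in marrow (14 of 25 higher, camera adjusted p = 0.603) and of 0.060 in the CSF (17 of 25 higher, camera adjusted p = 0.295). Laminins and other laminin receptors had medians of 0.023 in marrow (camera adjusted p = 0.411) and -0.011 in the CSF (0.656), where the direction of the test was upward against that median and a mean of -0.0012. The list of PI3K subunits and their proximal pathway had medians of 0.016 (camera adjusted p = 0.699) and -0.075 (0.243), and FOXO target genes, which this pathway holds down through AKT, 0.042 (0.411) and -0.12 (0.378).

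In control mice, immediate early genes had the smallest camera p of the lists compared between CSF and marrow, with the rise in control CSF replicates 1, 3 and 4 only. These transcripts, which cells induce within minutes of a stimulus or of handling, rose, higher in 20 of 22 members with a median of 0.23 (camera adjusted p = 3.80e-06), such as FOS at 0.77 ± 0.18 (SE, adjusted p = 0.181 in limma) and KLF6 at 0.41 (0.24). This call was lost with an adjusted p = 0.891 with an estimated correlation. The list's mean was 8.30, 8.43 and 8.02 in control CSF replicates 1, 3 and 4, against 7.68 to 7.83 in the other control CSF arrays and 7.59 to 7.86 in control marrow. Cytosolic ribosomal proteins fell, lower in 20 of 23 members with a median of -0.14 (camera adjusted p = 7.65e-05), with RPL19 at -0.29, and this too was lost, with an adjusted p = 0.891 with an estimated correlation. MBP, myelin basic protein, averaged 7.81 ± 0.28 (SD, n = 6) in control marrow and 8.75 ± 0.43 (SD, n = 6) in control CSF, 1.93-fold higher, with 5 of 6 CSF arrays above the marrow range (adjusted p = 0.13 in limma).

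No single gene passed in limma in control CSF against control marrow, whereas 3428 genes (10.2%), 1701 higher and 1727 lower, had an unadjusted p below 0.05, and the smallest adjusted p was 0.13. Besides MBP, the genes of smallest p included GPRASP3 at 0.54 ± 0.10 (SE, above all marrow arrays in 6 of 6, adjusted p = 0.13 in limma) and CERKL at 0.54 (adjusted p = 0.141 in limma). CERKL was dim, at 4.11 to 4.50 in control marrow and 4.51 to 5.03 in control CSF. LSM3, a splicing factor subunit, was at -0.44, below all marrow arrays in 6 of 6 (adjusted p = 0.181 in limma). In all, 5 lists passed in camera, 0 passed by fry, and each of the 5 had an adjusted p = 0.891 with an estimated correlation. Glycolysis genes rose, higher in 16 of 19 members with a median of 0.16 (camera adjusted p = 0.00554), with HK2, a hexokinase, at 0.36, and PFKFB3, a regulator of glycolytic flux, at 0.35. Oxidative phosphorylation genes fell, lower in 23 of 30 (median -0.086, camera adjusted p = 0.0192) and MHC class II genes in 12 of 13 (median -0.17, camera adjusted p = 0.0192), with HLA-DQA1 at -0.56. Adjusted over the list alone, limma gave 4 higher immediate early genes and 1 lower MHC class II gene. The number was 0 for glycolysis, oxidative phosphorylation and ribosomal proteins, of which 3, 5 and 6 had an unadjusted p below 0.05. With the intronic control level as a covariate, chosen after seeing the data, glycolysis had an adjusted p of 0.559 in camera. Left out singly, control CSF replicate 6 ended glycolysis (adjusted p = 0.0652), control marrow replicate 4 oxidative phosphorylation (0.17) and control marrow replicate 3 MHC class II (0.104), all in camera. Without control CSF replicate 1 or 4 there were 3 lists, and quantile normalization ended oxidative phosphorylation (adjusted p = 0.123 in camera). With array weights, limma called 109 genes.

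In treated mice too, MBP was higher in the CSF, and there it passed the threshold. It rose 2.38-fold, from 7.70 ± 0.18 (SD, n = 6) in treated marrow to 8.95 ± 0.44 (SD, n = 4) in treated CSF, with 4 of 4 CSF arrays above all marrow arrays (adjusted p = 0.0295 in limma). NDUFV2, the complex I subunit, fell by 0.69 (SE 0.13, adjusted p = 0.0347 in limma), XIAP, an inhibitor of apoptosis, by 0.78 (SE 0.15, adjusted p = 0.0447 in limma), and SLC30A9, of the zinc transporter family, by 0.75 (SE 0.14, adjusted p = 0.0358 in limma). HMGB3, a chromatin protein, fell by 0.65 (SE 0.13, adjusted p = 0.0441 in limma) and CDKN3, a phosphatase of cyclin-dependent kinases, by 0.62 (SE 0.11, adjusted p = 0.0336 in limma), while CCDC87 rose by 0.55 (SE 0.10, adjusted p = 0.0358 in limma). The treated CSF arrays lay outside the marrow range in 4 of 4 for each of these genes, as the naming rule required. Among all genes tested, 225 higher and 612 lower ones had no overlap between these groups. ITGA6 was at -1.0 ± 0.23 (SE, adjusted p = 0.0915 in limma), with 3 of 4 CSF arrays below the marrow range.

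Together, limma called 18 genes in treated CSF against treated marrow, 7 higher and 11 lower, 2 of them at least 2-fold, and 4748 genes (14.1%), 1732 higher and 3016 lower, had an unadjusted p below 0.05. All 18 calls were lost, leaving 0 genes in limma, when treated marrow replicate 1, treated marrow replicate 2 or treated CSF replicate 2 was left out, and MBP then had an adjusted p of up to 0.0905. Over all single omissions the log2 fold change of MBP stayed between 1.08 and 1.39. Its call ended in 3 of the 22 omissions, that of CDKN3 in 5 and that of NDUFV2 in 6. The calls of CCDC87, SLC30A9, HMGB3 and XIAP ended in 11, 12, 18 and 20. Without treated marrow replicate 4, treated CSF replicate 3 or treated CSF replicate 4 there were 7, 3 and 7 genes, without control CSF replicates 2 and 5 there were 11 and 10, and without control marrow replicate 2 or 3 there were 9. Array weights or the poly-A level as a covariate, the latter chosen after seeing the data, also gave 0 genes in limma.

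By camera, 6 lists differed between treated CSF and treated marrow, 1 higher and 5 lower. None of the 6 passed by fry, and each had an adjusted p = 0.918 with an estimated correlation. At the preset correlation, oxidative phosphorylation genes fell, lower in 30 of 30 members (median -0.21, camera adjusted p = 1.19e-07) and G2 and M phase genes in 28 of 28 (median -0.23, camera adjusted p = 1.51e-07). S phase genes fell, lower in 24 of 28 (median -0.21, camera adjusted p = 1.67e-04), with CLSPN at -0.47 and TYMS, thymidylate synthase, at -0.37. Ribosomal proteins fell, lower in 21 of 23 (median -0.16, camera adjusted p = 5.35e-04) and B lineage genes in 22 of 27 (median -0.16, camera adjusted p = 0.0244), with MME, which encodes CD10, at -0.58, or -0.35 without treated CSF replicate 2. Immediate early genes rose, higher in 17 of 22 (median 0.13, camera adjusted p = 0.0244), with FOS at 0.54 and ZFP36, an mRNA decay factor, at 0.43. Adjusted over the list alone, limma gave 8 lower oxidative phosphorylation genes, 4 lower genes each for S phase and for G2 and M phase, and 1 lower B lineage gene. It gave 0 immediate early and ribosomal protein genes, of which 3 and 6 had an unadjusted p below 0.05. Without treated CSF replicate 2 the first 2 lists kept an adjusted p of 0.0311 each, while S phase had 0.363, ribosomal proteins and immediate early genes 0.21 and B lineage genes 0.718 in camera. The 6 lists became 10 without treated marrow replicate 4 or treated CSF replicate 1 and 13 without treated CSF replicate 4, and quantile normalization ended S phase (0.431), ribosomal proteins (0.431) and B lineage (0.726).

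The site differences of control and treated mice, which share no array, had a Pearson correlation of 0.353 and a Spearman correlation of 0.344 across genes, which are not independent replicates, and the sign was the same for 61% of genes. Of the 18 genes called in treated mice, 16 had the same sign in control mice and 12 an unadjusted p below 0.05 there. MBP was higher in the CSF in both, and the test of the difference, which is the same as that between the treatment effects, gave 0 genes in limma, with 1551 at an unadjusted p below 0.05.

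Whether the inhibitor acted differently at the sites was tested gene by gene as a difference of the treatment effects, and no gene passed. Limma gave 0 genes, 1551 (4.61%) at an unadjusted p below 0.05, and a smallest adjusted p of 0.144, held by a gene outside the naming rule. By that rule the genes of smallest p included SBSN at 0.99 ± 0.23 (SE), TBC1D9 at 1.09 ± 0.26 (SE) and OGN, the matrix proteoglycan osteoglycin, at -0.99 ± 0.26 (SE). Each had an adjusted p of 0.916 in limma. By camera 8 lists were lower in the CSF effect than in the marrow effect. None of the 8 passed with fry, and each had an adjusted p = 0.779 with an estimated correlation. At the preset correlation, S phase genes (28 of 28 members, median -0.19, adjusted p = 5.58e-05), with CLSPN at -0.54, G2 and M phase genes (28 of 28, median -0.16, adjusted p = 7.58e-04) and histones (23 of 23, median -0.13, adjusted p = 0.0207) had every member lower. Glycolysis genes were lower in 18 of 19 (median -0.20, adjusted p = 0.00269), oxidative phosphorylation genes in 27 of 30 (median -0.15, adjusted p = 0.00397), and MYC targets in 24 of 26 (median -0.16, adjusted p = 0.0284). The p53 targets were lower in 18 of 22 (median -0.15, adjusted p = 0.0284), with CDKN1A, which encodes p21, at -0.60, and hypoxia genes in 21 of 26 (median -0.21, adjusted p = 0.0309). Without treated CSF replicate 2 all 8 calls ended, with an adjusted p of 0.129 to 0.998 in camera. Adjusted over the list alone, 0 genes passed in limma, with at most 2 per list at an unadjusted p below 0.05. Single omissions gave from 1 list, without treated CSF replicate 2, to 17, without treated CSF replicate 4.

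Markers of 12 other cell types that a mouse aspirate could hold, 245 list members read through human probes, were tested as lists. Apart from the neutrophil list in treated CSF, 0 of the 12 passed in camera in any of the 5 comparisons. Their medians lay between -0.076 and 0.077 for treated against control marrow (smallest adjusted p = 0.158 in camera) and between -0.040 and 0.19 for treated against control CSF. There the smallest value after the neutrophil list was that of fibroblasts, meninges and bone stroma, with 19 of 25 members higher (median 0.12, adjusted p = 0.0504 in camera). They lay between -0.083 and 0.14 for control CSF against control marrow (smallest adjusted p = 0.295 in camera). For treated CSF against treated marrow they lay between -0.033 and 0.13 (smallest adjusted p = 0.0871 in camera), and for the difference of the treatment effects between -0.016 and 0.12 (0.0576 in camera). TTN and SPP1, called in the CSF, stand on the lists of skeletal muscle and of fibroblasts and bone stroma. MBP stands on the list of oligodendrocytes and Schwann cells, whose 20 measured members had a median of 0.056 in control mice (adjusted p = 0.295 in camera) and of 0.079 in treated mice (adjusted p = 0.0919 in camera, 14 of 20 higher in the CSF).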

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

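The tests of the poly-A level of treated CSF replicate 2, of the site difference shared by control and treated mice, the tests of mouse cells and of less RNA for the treatment effect averaged over both sites, and that comparison itself, were chosen only after the result was seen. The rule that reads the T and NK cell markers was changed after their value was known: read by their median alone, or with a condition on their level, that explanation had counted as excluded.

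Treated CSF replicate 2 stood apart from the other arrays, with a median correlation with them of 0.967 against 0.988 to 0.989 in the rest of its group, a gap of 0.973 of the group's range. A larger response of this mouse to the inhibitor was not seen across genes as a set. Its deviation from the other treated CSF arrays correlated across brighter genes with the marrow treatment effect at -0.0157. In a check added later, with the trend on level removed, 48 of 114 genes called in the averaged effect without this array went further on it (median -0.105). That count is biased downward, since the other treated CSF arrays helped to pick these genes and also set the level compared. A larger response can therefore not be excluded, as also no gene passed in the marrow effect and CLECL1 and BTG3 did go further on this array. RNA of mouse cells may contribute, and the labels name no sort that would remove such cells. Of the 12 lists of other cell types, 7 deviated upward beyond the 95th percentile of 10000 random lists of like level. Among these were fibroblasts, skeletal muscle, megakaryocytes and erythroid cells. Of the 12 brightest members, 1 per list, CD7 (9.03), PF4 (7.40) and ACTA1 (9.43) alone were above all other arrays. Most of the 12 went the other way: TFRC (8.81) of the erythroid list, PDGFRA (8.94) of the fibroblast list, COL9A3 (8.97), NCF4, CTSS, CNP, GLUL and ERG lay below all other arrays. Little RNA in the library stays open and cannot be told apart from the rest, since the poly-A spikes lay 1.72 above the highest other array, which was at 8.27, within a range of 1.89 over the other 21. Its dim genes read higher and bright genes lower, with a Spearman correlation of -0.462 across genes, which lies beside every list shift of treated CSF.

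Control CSF and control marrow arrays differed in genes and in the level of intronic control probes, 3.77 ± 0.09 (SD, n = 6) against 3.46 ± 0.06 (SD, n = 6). The site of the cells is a candidate explanation. The site difference of treated mice, whose groups hold high and low intronic levels alike, correlated with that of control mice across genes at 0.353. This cannot favour the site over a technical difference common to CSF arrays. Poly-A spikes were higher in the CSF in control mice (7.63 against 7.01) and in treated mice (8.27 against 7.30). A difference in handling or labelling cannot be told apart from the site. The slope of each gene on the intronic level among the 6 treated marrow arrays correlated with the control site difference at 0.281. However, 8 of 100 reorderings of those levels gave as much (range -0.295 to 0.301). Both may act together, and no table separates them in control mice, where the intronic level follows the site.

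The treatment effect averaged over both sites had 150 genes past the threshold. Less RNA in the libraries of treated mice, as far as the poly-A spikes track it, did not account for most of the change. With the poly-A level as a covariate the median gene kept 92.7% of its change and all 150 kept their sign. This cannot exclude an effect of RNA amount, since the level is a mean of 4 features and 1 array, treated CSF replicate 2 (9.99), lies far above the rest. With the covariate 39 of the 150 still passed, as the median absolute log2 change went from 0.515 to 0.476 and the median SE from 0.105 to 0.109. Of the 111 lost calls, 94 had a smaller change and 91 a larger SE, 74 having both, and the part of the lost degree of freedom was not separated. A smaller share of mouse NK cells, or of T cells, which SCID mice largely lack, in treated mice stays open for genes of those cells and cannot be told apart, since the list of their markers had a median log2 change of 0.062 with 14 members higher and 7 lower and a median over members that go both ways decides nothing; of the 7, GZMA and ZAP70 passed in limma. The action of the inhibitor on the leukaemia cells stays open as untested.

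Random splits of the compared arrays, 100 per comparison with the real one included, showed whether chance can be excluded. It was excluded for the genes past the threshold in the CSF treatment effect (1 split with as many, real 36, highest other 2) and in the averaged effect (1, real 150, highest other 1). In the site difference of treated mice 2 splits gave as many (real 18), but another split called 1873 genes. A count that unstable cannot decide there, and the reason for it was not tested. Chance was also excluded for the genes at an unadjusted p below 0.05 in the site difference of control mice (1, real 3428, highest other 2978). It was not excluded for the genes at an unadjusted p below 0.05 in the marrow treatment effect (9, real 1637, highest other 2346) and in the difference of the treatment effects (40, real 1551, highest other 5668). For the number of lists it was excluded nowhere: 27 splits gave as many in marrow (real 8, highest other 20), 39 in the CSF (real 15, highest other 27). As many came from 49 splits for site in control mice (real 5, highest other 19), and 75 for site in treated mice (real 6, highest other 30), then 56 for the difference of the treatment effects (real 8, highest other 26) and 20 for the averaged effect (real 17, highest other 28).

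Single arrays lay far from the rest of their group for some named genes, as a gap to the nearest array divided by the group's range. This held in 12 of 188 groups for genes, 5 of 84 for lists and 3 of 32 for quality measures, where chance gives about 1 in 20. In the marrow controls, the gap was 0.665 for CD180 (6.63) and 0.698 for PTPN6 (9.80) in replicate 4 and 0.645 for OLFML2B (4.46) in replicate 2. In treated marrow it was 0.659 for HMGB3 (8.69) and 0.63 for FYN (7.57) in replicate 4, 0.689 for OLFML2B (7.37) and 0.716 for VPS26B (8.14) in replicate 3, and 0.661 for XIAP (7.98) in replicate 6. In the CSF controls it was 0.694 for ADAMTS9 (6.14) in replicate 4 and 0.646 for KIT (7.54) in replicate 1, and in treated CSF 0.964 for BTG3 (5.08) in replicate 2 and 0.938 for SLC2A3 (7.58) in replicate 1. Among list means the gap was 0.949 for MYC targets in treated CSF replicate 2, 0.787 for heat shock proteins in control marrow replicate 4, 0.774 for neutrophil markers in control marrow replicate 2. It was 0.665 for B lineage genes and 0.723 for small nucleolar RNAs in control CSF replicate 1. Control CSF replicate 1 also had a gap of 0.695 in the median over all genes and of 0.788 in its median correlation with the other arrays (0.984).

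The treatment effect differed between CSF and marrow in camera for 8 lists, with adjusted p values of 5.58e-05 for S phase, 7.58e-04 for G2 and M phase, 0.00269 for glycolysis, 0.00397 for oxidative phosphorylation, 0.0207 for histones, 0.0284 for MYC targets, 0.0284 for p53 targets and 0.0309 for the hypoxia response, and none of the 8 passed with fry or with an estimated correlation (adjusted p = 0.779 with an estimated correlation), and all 8 calls ended without treated CSF replicate 2. Among the 99574 features without exactly 1 symbol, which are not counted in the report, a separate limma fit of the same comparisons called 3 in the CSF treatment effect (2 higher and 1 lower), 2 in the site difference of treated mice (both higher) and 25 in the averaged effect (10 higher and 15 lower).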

How the results depend on the processing

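The tests on the averaged effect, with both divergent arrays (control CSF replicate 1 and treated CSF replicate 2) left out and with a covariate were chosen only after the result was seen. Causes were not tested except where the construction shows them, as with fewer arrays, fewer genes or a stricter rule. Of the named single genes under other settings, 1767 values kept direction and side of the threshold, 166 no longer passed, 45 newly passed and 2 reversed; with 1 array left out these were 3595, 238, 38 and 1. The reversals were RPS9 for site in control mice with the mean of its clusters (0.17), ITGA6 in the difference of the treatment effects with the intronic covariate (0.015) and PIK3CD for site in treated mice without treated CSF replicate 1 (-0.011, up to 0.20 without treated CSF replicate 2). Counts of genes, all against 0 in marrow, 36 in the CSF, 0 for site in control mice, 18 for site in treated mice, 0 for the difference and 150 for the averaged effect, moved as follows.

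Fitting only the groups compared gave 7 in the CSF and 2 for site in treated mice, and trended robust moderation 2 in marrow and 65 in the CSF. Array weights gave 8 in marrow, 11 in the CSF, 109 for site in control mice and 0 for site in treated mice. The upper part of genes by mean gave 5, 74, 2 and 66 (4.55% higher) for these, 334 for the averaged effect with 11 lists, and correlations of 0.441 for treatment and 0.455 for site. Quantile normalization gave 1 in marrow, 7 for site in treated mice (71.4% higher against 38.9%), 1 for the difference, and 29.7% higher for the averaged effect against 16.7%; median centring gave 4 in marrow and 10 for site in treated mice (70% higher). All clusters of the table gave 8 in the CSF, 2 for site in treated mice and 66 averaged, and a fold of at least 2 gave 16, 2 and 10. Replicate number as a block gave 6, 2 and 75. Within treatment it gave 2 for site in treated mice as a fixed and 2 in marrow as a random block (consensus correlation -0.106). Whether the numbers mark mice is not given. Without both divergent arrays there were 2 in marrow, 7 in the CSF, 1 for site in control mice, 0 for site in treated mice and a site correlation of 0.426. The intronic covariate gave 3 in marrow and 4 in the CSF, and the poly-A covariate 6 in the CSF, 0 for site in treated mice and 41 averaged.

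Lists went from 8, 15, 5, 6, 8 and 17, in the order of the comparisons, to 4, 8, 8, 3, 1 and 5 with quantile normalization, and to 0 in all 6 with an estimated correlation and with fry. Without both divergent arrays there were 9 in the CSF, 2 for site in treated mice, 1 for the difference and 11 averaged. The intronic covariate gave 15 in marrow, 10 for site in control mice and 0 for the difference, and the poly-A covariate 4 in marrow, 3 for site in treated mice and 5 for the difference. With each array left out in turn, genes ranged from 0 to 6 in marrow, 6 to 98 in the CSF, 0 to 1 and 0 to 27 for site in control and treated mice, 0 to 0 for the difference and 90 to 230 averaged. Lists ranged from 4 to 9, 7 to 19, 3 to 6, 2 to 13, 1 to 17 and 9 to 22, ITGA6 from -0.55 to -0.33 in marrow and -1.04 to -0.59 in the CSF, and the correlations from 0.191 to 0.330 for treatment and 0.278 to 0.401 for site.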

Other observations

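The comparison described here, the treatment effect averaged over both sites, and its tests were chosen only after the result was seen.

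Averaged over marrow and CSF, AK5, TTN, CD96 and CLECL1 were lower in treated mice. Limma called 150 genes, 25 higher and 125 lower, 10 of them at least 2-fold, with 4509 at an unadjusted p below 0.05. AK5 fell by 1.46 on the log2 scale (SE 0.15, adjusted p = 1.42e-05), TTN by 1.07 (adjusted p = 2.70e-05), CD96 by 1.5 (adjusted p = 3.71e-05) and CLECL1 by 1.97 (adjusted p = 6.43e-05). The phosphatase PTPRC fell by 0.80 (adjusted p = 4.28e-04), LAT2, an adaptor of immune receptors, by 0.61 (0.00144), and LYN, a Src-family kinase, by 0.49 (0.0102). PTPN6, the phosphatase SHP-1, fell by 0.69 (0.0194) and ZAP70, a receptor-proximal kinase, by 0.47 (0.0283), while FYN rose by 0.94 (4.79e-04). CD72 fell by 0.63 (0.0146), CD180, a Toll-like receptor homologue, by 1.11 (0.0165), and MS4A1 by 0.47 (0.0371). CD69, an activation marker, fell by 1.06 (0.0418), IRF8, a B cell and myeloid transcription factor, by 0.78 (0.00841), ID2 by 1.0 (0.00111), SPP1 by 1.05 (5.19e-04) and IFITM1 by 0.62 (0.0117). MYOF rose by 0.71 (0.00136), ENPP2, which makes lysophosphatidic acid, by 0.91 (0.00306) and KIT, the stem cell factor receptor, by 0.81 (0.0146), these being adjusted p values of limma. Over the 22 single omissions, the calls of CD69, MS4A1 and ZAP70 ended in 14, 12 and 9, with adjusted p values of up to 0.0822, 0.0765 and 0.0634, while their changes stayed between -1.14 and -0.93, -0.50 and -0.42, and -0.52 and -0.43. ITGA6 was at -0.63 (adjusted p = 0.0655 in limma).

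Of the 45 lists, 17 passed in camera for the averaged effect, 3 higher and 14 lower, with 0 by fry. None passed with an estimated correlation, the smallest value being an adjusted p = 0.562 with an estimated correlation. At the preset correlation, oxidative phosphorylation genes fell, lower in 30 of 30 members (median -0.15, adjusted p = 2.34e-08), MYC targets in 24 of 26 (median -0.19, adjusted p = 2.59e-08), ATF4 targets in 23 of 25 (median -0.20, adjusted p = 2.97e-06) and ribosomal proteins in 23 of 23 (median -0.11, adjusted p = 9.08e-05). Heat shock proteins rose, higher in 11 of 14 (median 0.15, adjusted p = 9.93e-04). Adjusted over the list alone, 12 MYC targets and 10 ATF4 targets were lower in limma. G2 and M phase (adjusted p = 3.16e-05), S phase (6.80e-05) and histone genes (8.54e-04) were lower and kept an adjusted p below 0.05 with any 1 array left out. Without treated CSF replicate 2, glycolysis (0.0632), B lineage (0.127), small nucleolar RNA (0.0536), neutrophil (0.0907), B cell receptor (0.0723), axon guidance (0.0771), fatty acid synthesis (0.197), interferon (0.328) and hypoxia lists (0.419) no longer passed in camera. With quantile normalization 5 of the 17 lists passed, those of MYC targets, oxidative phosphorylation, ATF4 targets, heat shock proteins and small nucleolar RNAs, and the others had adjusted p values of 0.0599 to 0.224 in camera. For single genes, 87 of the 150 still passed without that array, all 150 kept their sign, and the median gene kept 91.2% of its change.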
